A study of Saccharomyces cerevisiae with 90 samples.

How the data were processed

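Gene expression was measured on Affymetrix arrays in 90 samples, and all columns of both value tables were used. The first table, of 10 h colonies, holds 70 arrays in 21 groups. Its deposited values are on the log2 scale, made with RMA per the submitters' processing notes in the labels. Array medians were 6.27 to 6.68, and which arrays were normalized together is not stated. The second table, of cells from SC medium, holds 20 arrays in 10 groups. Its deposited values are linear intensity in whole numbers from 1 to 16048, and array medians were 28 to 30. How these intensities were made is not given in the sources used here. Between 6.77 and 25.6 percent of the values of an array were at 1, so weak genes could not be followed below that floor. The number of arrays limits the precision, and p-values measure the spread between samples, part of which may be technical. Changes were never compared across the tables.

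Probe sets were joined to genes by the array annotation, with gene names from the RefSeq annotation of assembly R64. In the first of the tables, 5668 of 6739 probe sets pointed to 1 gene (166 to several and 905 to none), giving 5562 genes. In the second, 5595 of 6178 did (583 to none), giving 5560 genes. Probe sets with several genes or none were left out. Where a gene had several probe sets (80 and 34 genes), the one with the highest mean over all arrays was used. As a check of the join, the mean levels of 5328 genes in both tables had a Spearman correlation of 0.753 across genes. The first table was used as deposited. In the second, arrays were scaled to the same median (factors 0.96 to 1.03), values under the 10th percentile (0.993) were set to it, and log2 was taken.

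For each table, limma 3.58.1 in R 4.3.3 fitted all group means at once, with residual degrees of freedom of 49 and 10 and eBayes without trend. Comparisons were contrasts of these means: the filamentous against the yeast form of the wild type, each deletion strain against the filamentous wild type, and, for each pair of deleted genes, the change of the double mutant minus the sum of the changes of the single mutants. In SC medium each mutant was compared with the wild type, ira1 with ira1RA, and 2 mM with 0 mM cAMP. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, over all its genes. These tests are two-sided. The samples, the comparisons, the gene lists and the main alternatives were fixed before the data were examined.

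A total of 23 gene lists (pathways, regulons and cell type markers) were tested with camera, with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. The results of 1 of the lists are not reported here. Of 228 calls, 25 held with an estimated correlation. Genes are named by a rule: the altered genes, the markers and FLO11, PTR2, OPT2, SUC2, PHD1 and IME1; the largest changes among named genes that passed and whose arrays did not overlap (up to 10 each way between the forms, 7 for a single deletion, 5 in SC medium and 2 for a pair, with overlap allowed for departures from the sum); and up to 4 members of a list. In SC medium, genes with any value at 1 in the groups compared were left out of the largest changes, since such a fold depends on the floor.

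Replicate numbers could stand for shared days. The correlation of residuals over all genes was computed for arrays with the same number in the 20 comparisons with 3 or more pairs. Only between the forms of the wild type did each same-number pair exceed 0.1 (0.113 to 0.254), so the blocked count is given there. Over all comparisons these correlations ran from -0.377 to 0.443.

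The calls were tested on simulated data with 200 changed genes per comparison. Between the forms of the wild type, 31.3 percent of changes of 0.5 on the log2 scale, 91.0 percent of changes of 1 and 98.5 percent of changes of 2 were recovered. For tec1 the shares were 32.8, 91.0 and 100 percent. For the tec1 and cup9 departure from the sum they were 8.96, 73.1 and 98.5 percent. For ira1 in SC medium they were 0, 0 and 30.3 percent, and for 2 mM against 0 mM cAMP 0, 1.49 and 10.6 percent. Few simulated changes of 2 or less were thus recovered in that table. The adjusted threshold eases as more genes pass, and the real cAMP comparison called 1092 genes against 8 in its simulation. Smaller real changes could therefore pass there.

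Alternatives were quantile normalization, a filter at the 25th percentile of mean level, the mean of the probe sets of a gene, a fit of only the groups compared, eBayes with trend and robust, the replicate number as a block, leaving out each array in turn, and, in SC medium, a floor at the 25th percentile and the slope over the cAMP concentration. Each called list was also tested without each array, after seeing the data. Where an arm was left with 1 array, it was assumed to vary like the other groups. Alternatives chosen after seeing the data were leaving out the libraries labelled tec1 replicate 1 and cup9 replicate 4, a floor at 20, only wild-type arrays 1 and 2 or only 3 and 4 in SC medium, and the array set as a block. Up to 100 other splits of the same arrays were drawn per comparison of at least 3 arrays a group. For departures from the sum, residuals of the model without a departure were also permuted in 100 draws, and the splits of tec1 and cup9 and the draws of their pairs were repeated without the libraries labelled tec1 replicate 1 and cup9 replicate 4, tests chosen after seeing the data.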

Results

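The series measured mRNA levels with Affymetrix arrays in budding yeast of a strain background that grows as filaments of elongated cells when nitrogen is scarce. A first table holds 70 arrays of colonies grown for 10 h on agar. The wild type was measured as yeast-form cells on synthetic complete medium (6 arrays) and as filamentous-form cells on low-ammonium medium (3 arrays). All mutants of this table grew on low-ammonium medium. By their labels, 6 strains each lack 1 transcription factor (TEC1 and CUP9, 5 arrays each, and SFL1, SOK2, SKN7 and YAP6, 3 arrays each). A further 13 strains are labelled as lacking a pair of them (3 arrays each). Some libraries read against their labels, as given next. A second table holds 20 arrays of cells from synthetic complete (SC) medium with altered Ras and cyclic AMP signalling: 4 wild-type arrays, 2 for each of 5 mutants, and 6 for strains labelled ras1 ras2 pde2 given 0, 0.5, 1 or 2 mM cAMP (2, 1, 1 and 2 arrays). Per the labels the 0 mM arrays are of another strain number, with a plasmid, than those of the other concentrations. The number of arrays limits the precision. Log2 changes are given with their standard error (SE) and levels with their standard deviation (SD). For each gene named as a largest change between a pair of groups, the arrays of the groups did not overlap.

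The deleted genes were read first. TEC1, which encodes a transcription factor of the filamentation pathway, stood at 8.34 ± 0.25 (SD, n = 3) in filamentous wild-type colonies and between 4.79 and 5.37 in 4 of 5 tec1 arrays, but at 8.68 in the library labelled tec1 replicate 1. CUP9, which encodes the repressor of the peptide transporter gene PTR2, stood at 7.78 ± 0.06 (SD, n = 3) in the wild type and between 3.68 and 4.34 in 4 of 5 cup9 arrays, but at 8.21 in the library labelled cup9 replicate 4. That library read 4.57 for TEC1, and the library labelled tec1 replicate 1 read 4.07 for CUP9. SOK2 (-4.07 ± 0.20, adjusted p = 5.09e-23), SKN7 (-3.53 ± 0.15, adjusted p = 3.78e-26) and SFL1 (-1.47 ± 0.20, adjusted p = 1.24e-07) fell in their deletion strains. YAP6 was dim in the wild type (4.11 ± 0.24, SD, n = 3) and fell in the yap6 strain (-1.62 ± 0.22, adjusted p = 1.21e-07). CUP9 did not pass in the strain labelled cup9-yap6, where it stood at 8.17 ± 0.18 (SD, n = 3) against 9.26 ± 0.03 in yap6 colonies.

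**Figure D1:**
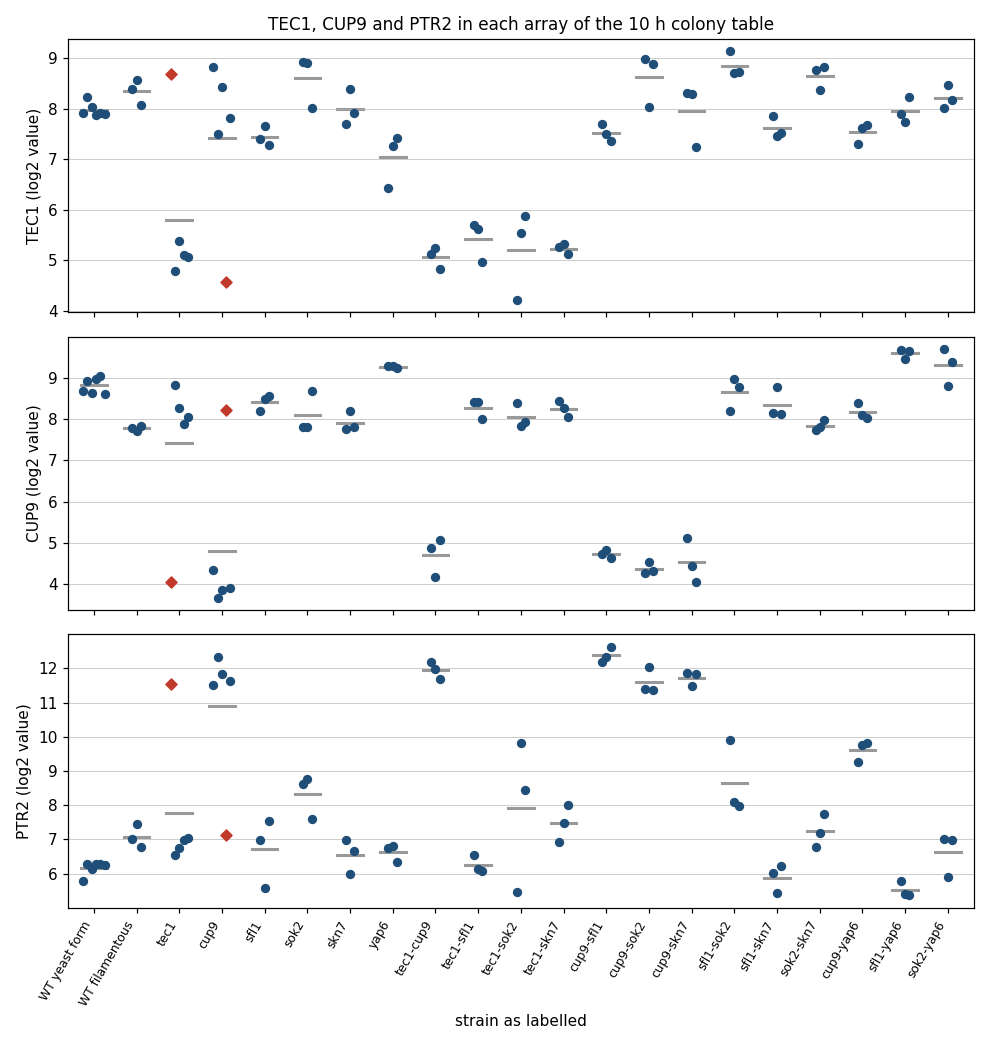
Log2 values of TEC1, CUP9 and PTR2 (vertical axes) in each of the 70 arrays of the 10 h colony table, by strain as labelled. Each point is an array, the grey bar is the mean of the strain, and the red diamonds mark the libraries labelled tec1 replicate 1 and cup9 replicate 4, where TEC1 read 8.68 and 4.57.

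The filamentous form of the wild type was compared with its yeast form to ask which genes accompany filamentous growth on low ammonium. Form and medium changed together, so a change with the form cannot be told apart from a response to the medium. Genes for scavenging poor nitrogen sources were higher in filamentous colonies, among them DAL5 for allantoate uptake (4.67 ± 0.30, adjusted p = 5.55e-19), DAL7 for allantoin breakdown (4.08 ± 0.29, adjusted p = 2.32e-17) and DAL80, a regulator of nitrogen genes (2.91 ± 0.40, adjusted p = 4.34e-08). In the list of nitrogen catabolite repressed genes, 10 of 18 members rose and 1 fell (11 rose and 1 fell adjusted over the list alone), median 1.49 (adjusted p = 1.23e-08, or 0.0898 with an estimated correlation). YCT1, a cysteine transporter gene, rose (3.52 ± 0.24, adjusted p = 2.81e-18), as did FLO11 for the cell-surface flocculin of filaments (2.20 ± 0.57, adjusted p = 0.00144) and SOK2 (1.12 ± 0.18, adjusted p = 1.34e-06). Lower in filamentous colonies were TPO2 for a polyamine exporter (-5.64 ± 0.52, adjusted p = 4.06e-13), BAP2 for branched-chain amino acid uptake (-4.38 ± 0.29, adjusted p = 1.44e-18) and TDH1 for a glycolytic dehydrogenase (-4.04 ± 0.39, adjusted p = 2.52e-12). So was HSP30 for a stress-induced membrane protein (-3.67 ± 0.54, adjusted p = 2.81e-07). Of the iron regulon, 13 of 14 members fell (14 adjusted over the list alone), median -1.35 (adjusted p = 3.33e-11, or 0.0098 with an estimated correlation). TIS11, which encodes a protein that degrades mRNAs when iron is low, was among them (-3.55 ± 0.26, adjusted p = 9.42e-17). Of the general stress genes driven by Msn2 and Msn4, 16 of 21 members fell (18 adjusted over the list alone), median -1.32 (adjusted p = 7.27e-08, or 0.188 with an estimated correlation). Of the ribosome biogenesis genes, 14 of 22 members rose (18 adjusted over the list alone), median 0.66 (adjusted p = 0.000814, or 0.545 with an estimated correlation). In all, 1203 higher and 1293 lower of 5562 genes passed with limma, and 2307 with the replicate number as a block.

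FLO11 had a wide range among the strains, from 8.43 ± 0.27 (SD, n = 6) in yeast-form to 10.63 ± 0.47 (SD, n = 3) in filamentous wild-type colonies and 13.52 ± 0.06 (SD, n = 3) in sfl1 colonies. Against the filamentous wild type it rose without SFL1, which encodes a repressor of flocculation genes (2.89 ± 0.65, adjusted p = 0.00115), and in each sfl1 pair, from 2.73 (sfl1-yap6) to 3.09 (cup9-sfl1). It rose in the yap6 strain (2.09 ± 0.65, adjusted p = 0.0156), but not without 1 of some arrays (adjusted p = 0.0742 without wild-type array 2 and 0.0642 without yap6 array 1). In cup9-yap6 it rose by 2.30 (adjusted p = 0.00767). The call in cup9-sok2 (2.53 ± 0.65, adjusted p = 0.0115) was lost at adjusted p = 0.0541 without wild-type array 2 and 0.119 without cup9-sok2 array 2. In sok2-skn7 (2.35 ± 0.65, adjusted p = 0.021) it was lost at adjusted p = 0.082 or 0.0606 without wild-type array 2 or 3 and 0.0871 or 0.106 without sok2-skn7 array 1 or 2. In sok2-yap6 (2.06 ± 0.65, adjusted p = 0.0245) it was lost at adjusted p = 0.111 or 0.0506 without wild-type array 2 or 3 and 0.11 or 0.0609 without sok2-yap6 array 1 or 3. FLO11 fell in tec1-skn7 (-2.04 ± 0.65, adjusted p = 0.0152), but not at adjusted p = 0.0559 or 0.0556 without wild-type array 1 or 3 and 0.0526 or 0.0679 without tec1-skn7 array 1 or 3. The sok2 strain itself gave 2.02 ± 0.65, adjusted p = 0.131. FLO11 was not called in tec1, where its arrays spread from 8.18 to 12.03. Nor was it called in tec1-cup9, though its arrays there (8.60, 8.92 and 8.83) all lay below the filamentous wild type (10.09 to 10.94).

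**Figure D2:**
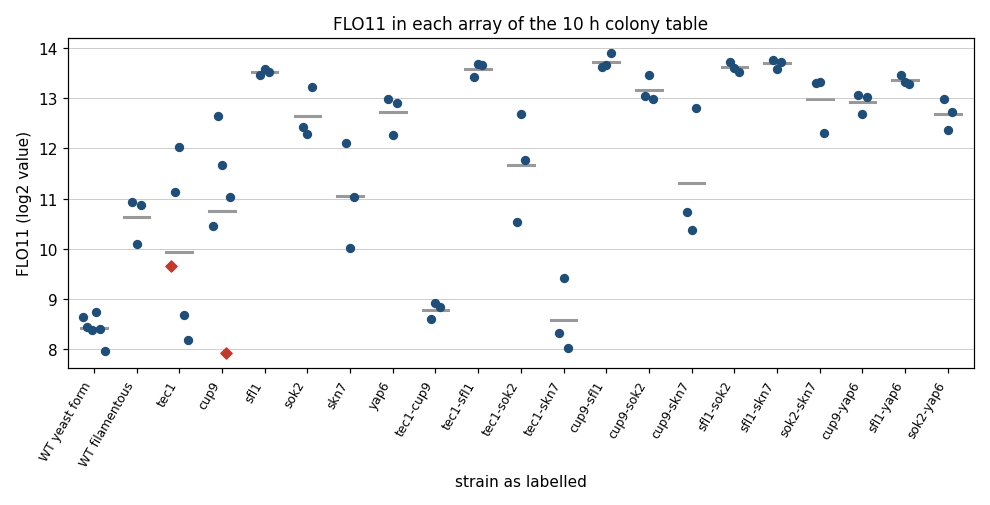
Log2 value of FLO11 (vertical axis) in each of the 70 arrays of the 10 h colony table, by strain as labelled. Each point is an array, the grey bar is the mean of the strain and the red diamonds are the libraries labelled tec1 replicate 1 and cup9 replicate 4. FLO11 stood at 8.43 in yeast-form and 10.63 in filamentous wild-type colonies and at 13.52 in sfl1 colonies.

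Loss of TEC1 asked which genes need this activator in filamentous colonies. SRD1, which encodes a protein of pre-rRNA processing, fell (-2.32 ± 0.36, adjusted p = 0.000199), as did TEC1 itself (-2.54 ± 0.52, adjusted p = 0.0152). NFG1, a gene of the filamentation list, fell as well, by 2.13 ± 0.44 with an adjusted p of 0.0152, though its arrays overlapped. Of the filamentation MAPK genes, 1 of 12 members fell (4 adjusted over the list alone), median -0.42 (adjusted p = 3.23e-11, or 2.02e-06 with an estimated correlation). In all, 4 higher and 3 lower genes passed, among them JIP4 (0.58 ± 0.11, adjusted p = 0.0119) and MLP2 (0.99 ± 0.21, adjusted p = 0.0174). Without the library labelled tec1 replicate 1, TEC1 fell by 3.26 (adjusted p = 1.65e-06). That library stood out by its TEC1 value, so this p-value depends on the choice to leave it out. The TEC1 call was lost at adjusted p = 0.0973, 0.197 or 0.0695 without wild-type array 1, 2 or 3 and 0.108 or 0.0761 without tec1 array 2 or 4. In a fit of only the groups compared SRD1 (adjusted p = 0.0783, from 7.71e-18 to 0.0783 over all alternatives), TEC1 (0.144, from 1.01e-12 to 0.197) and MLP2 (0.129, from 0.0126 to 0.435) did not pass. JIP4 did not pass with quantile normalization (adjusted p = 0.0577, from 0.00617 to 0.197). JIP4 was lost at adjusted p = 0.197 or 0.0695 without wild-type array 2 or 3, and MLP2 at adjusted p = 0.435 or 0.0695 without wild-type array 2 or 3 and 0.158 without tec1 array 2. The total was 3, 1 or 1 without wild-type array 1, 2 or 3 and 14, 2, 3 or 13 without tec1 array 1, 2, 4 or 5, and 14 without the libraries labelled tec1 replicate 1 and cup9 replicate 4.

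Loss of CUP9 raised PTR2, the peptide transporter gene that Cup9 represses (3.80 ± 0.74, adjusted p = 0.00265), and COA4, for assembly of cytochrome oxidase (1.04 ± 0.19, adjusted p = 0.00226). COA4 was also called in tec1 (0.86 ± 0.19, adjusted p = 0.0433), against the same wild-type arrays. CUP9 itself fell (-2.98 ± 0.57, adjusted p = 0.00265). Without the library labelled cup9 replicate 4, CUP9 fell by 3.83 (adjusted p = 7.02e-08) and PTR2 rose by 4.74 (adjusted p = 1.72e-06). That library stood out by both genes, so these p-values depend on the choice to leave it out. Of the TCA cycle and respiration genes, no member of 25 passed singly (9 rose adjusted over the list alone), median 0.33 (adjusted p = 1.68e-06, or 0.207 with an estimated correlation). Of the filamentation MAPK genes, no member of 12 passed singly (2 fell adjusted over the list alone), median -0.28 (adjusted p = 4.94e-05, or 0.00506 with an estimated correlation). The library labelled cup9 replicate 4, which read TEC1 at 4.57, is in these values. Without both libraries at odds with their labels, the filamentation MAPK list had a median of -0.23 (adjusted p = 0.00528, or 0.0645 with an estimated correlation). Of the sulfur assimilation genes, no member of 13 passed singly (none adjusted over the list alone), median -0.39 (adjusted p = 4.94e-05, or 0.304 with an estimated correlation). In a fit of only the groups compared, CUP9 (adjusted p = 0.178, from 1.32e-19 to 0.178 over all alternatives), PTR2 (0.143, from 1.95e-10 to 0.143) and COA4 (0.0717, from 0.00175 to 0.0717) did not pass. In all, 15 higher and 4 lower genes passed. PTR2 was lost at adjusted p = 0.0572 without wild-type array 3. The total was 6, 11 or 6 without wild-type array 1, 2 or 3 and 10, 48 or 9 without cup9 array 2, 3 or 5, and 23 without the libraries labelled tec1 replicate 1 and cup9 replicate 4.

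Loss of SFL1 raised the flocculin gene FLO10 (5.07 ± 0.24, adjusted p = 2.97e-24) and PRM7, a pheromone-regulated gene (4.67 ± 0.47, adjusted p = 4.44e-11). DDR48 for a stress protein (3.17 ± 0.22, adjusted p = 3.37e-17) and GPD1 for glycerol synthesis (2.98 ± 0.30, adjusted p = 4.44e-11) rose too. Of the flocculins measured, FLO1, FLO10 and FLO11, 2 of 3 members rose (2 adjusted over the list alone), median 2.89 (adjusted p = 0.000119, or 0.00723 with an estimated correlation). HPF1, a cell wall mannoprotein gene, fell (-2.70 ± 0.55, adjusted p = 0.000381), as did HAP4, an activator of respiratory genes (-1.65 ± 0.31, adjusted p = 0.000123). Among general stress genes, 10 of 21 members rose (11 adjusted over the list alone), median 0.79 (adjusted p = 8.01e-07, or 0.447 with an estimated correlation). Of the iron regulon, 8 of 14 members rose and 1 fell (8 rose and 2 fell adjusted over the list alone), median 0.71 (adjusted p = 0.000799, or 0.447 with an estimated correlation). Among ribosome biogenesis genes, 8 of 22 members fell (9 adjusted over the list alone), median -0.65 (adjusted p = 0.00097, or 0.654 with an estimated correlation). In all, 572 higher and 805 lower genes passed, and the total was 903 or 875 without wild-type array 1 or 3 and 485 without sfl1 array 3.

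Loss of SOK2, which encodes a repressor in the cAMP pathway, raised TPO2 (5.30 ± 0.60, adjusted p = 6.1e-09), HPF1 (3.36 ± 0.55, adjusted p = 5.59e-05) and PHD1, for an activator of filamentous growth (2.26 ± 0.26, adjusted p = 6.46e-09). ADR1, an activator of genes for growth without glucose, rose (2.05 ± 0.26, adjusted p = 9.16e-08), and so did HXT6 for high-affinity glucose uptake (1.83 ± 0.35, adjusted p = 0.000669). SUL1, the sulfate permease gene (-1.70 ± 0.30, adjusted p = 0.000268), and the glucose transporter gene HXT2 (-1.59 ± 0.30, adjusted p = 0.000737) fell. Of the sulfur assimilation genes, 1 of 13 members fell (2 adjusted over the list alone), median -0.45 (adjusted p = 3.2e-06, or 0.4 with an estimated correlation). PHD1 rose in every sok2 pair too, from 1.79 (sok2-yap6) to 2.90 (tec1-sok2). In all, 46 higher and 19 lower genes passed, and the total was 36, 38 or 40 without wild-type array 1, 2 or 3 and 37 or 33 without sok2 array 1 or 2.

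Loss of SKN7, a regulator of the oxidative and cell wall stress responses, lowered PUF6 (-1.73 ± 0.36, adjusted p = 0.000688), RLP24 (-1.68 ± 0.34, adjusted p = 0.000534) and UTP23 (-1.77 ± 0.35, adjusted p = 0.000486), all for making ribosomes. Of the ribosome biogenesis genes, 16 of 22 members fell (17 adjusted over the list alone), median -0.88 (adjusted p = 0.000209, or 0.627 with an estimated correlation). COS8, a subtelomeric membrane protein gene (2.24 ± 0.31, adjusted p = 3.15e-06), ATF2 for acetate ester formation (1.43 ± 0.25, adjusted p = 0.000165) and SUC2 for invertase (1.09 ± 0.27, adjusted p = 0.002) rose. Of the iron regulon, 10 of 14 members rose (10 adjusted over the list alone), median 0.67 (adjusted p = 0.000551, or 0.51 with an estimated correlation). Of the glycolysis and fermentation genes, 8 of 15 members rose (8 adjusted over the list alone), median 0.29 (adjusted p = 0.00205, or 0.51 with an estimated correlation). The list of oxidative stress genes under Skn7 was not called (median 0.01). In all, 891 higher and 1170 lower genes passed, and the total was 658 without skn7 array 1.

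Loss of YAP6, which encodes a factor related to the stress regulator Yap1, raised TPO2 (6.68 ± 0.60, adjusted p = 1.67e-12), UGA4 for uptake of GABA (4.69 ± 0.77, adjusted p = 6.72e-06) and PUT4 for uptake of proline (3.81 ± 0.67, adjusted p = 2.21e-05). It also raised CAR1 for arginine breakdown (3.59 ± 0.50, adjusted p = 1.77e-07) and HSP30 (4.53 ± 0.62, adjusted p = 1.67e-07). Of the nitrogen catabolite repressed genes, 12 of 18 members rose (13 adjusted over the list alone), median 0.85 (adjusted p = 3.1e-07, or 0.548 with an estimated correlation). Of the general stress genes, 10 of 21 members rose (10 adjusted over the list alone), median 0.85 (adjusted p = 0.00127, or 0.605 with an estimated correlation). SUL1 (-1.88 ± 0.30, adjusted p = 4.84e-06) and the YAP6 relative CIN5 (-1.81 ± 0.40, adjusted p = 0.000599) fell. Of the sulfur assimilation genes, 5 of 13 members fell (7 adjusted over the list alone), median -0.64 (adjusted p = 0.00105, or 0.605 with an estimated correlation). IME1, the activator gene of meiosis, rose (0.70 ± 0.17, adjusted p = 0.00166). In all, 700 higher and 615 lower genes passed, and the total was 869 without wild-type array 3 and 815 without yap6 array 1.

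The changes in sfl1, skn7 and yap6 colonies resembled each other across genes. Between sfl1 and skn7, 329 genes rose in both, against 91.6 by chance, 545 fell in both, against 169, and 7 went opposite ways. Between sfl1 and yap6, 231 rose in both (72.0 by chance), 346 fell in both (89.0) and 6 went opposite ways. Between skn7 and yap6, 276 rose in both (112 by chance), 385 fell in both (129) and 16 went opposite ways. Across genes, which are not independent replicates, the log2 changes had Pearson r = 0.716, 0.621 and 0.561 in these 3 pairs. Simulated groups with no true change and 3 shared control arrays gave r = 0.474 on average in 1000 simulations. They were drawn from residuals of the low-ammonium arrays, so an offset common to the real wild-type arrays could not appear. These 3 arrays cannot be divided between the strains, so part of the excess may come from them.

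In the strains lacking a pair of factors, PTR2 rose wherever CUP9 was deleted with TEC1 (4.87 ± 0.82, adjusted p = 0.000151), SFL1 (5.30 ± 0.82, adjusted p = 4.26e-06), SOK2 (4.51 ± 0.82, adjusted p = 0.000255) or SKN7 (4.64 ± 0.82, adjusted p = 0.000373). In cup9-yap6 it rose as well (2.53 ± 0.82, adjusted p = 0.0203), with the call lost at adjusted p = 0.0533 or 0.0717 without wild-type array 1 or 3 and 0.0555 or 0.0575 without cup9-yap6 array 2 or 3. FLO10 rose in cup9-sfl1 (5.76), sfl1-sok2 (6.01) and sfl1-skn7 (5.69), with adjusted p of 5.42e-27, 6.31e-28 and 6.4e-27. Of the flocculins in sfl1-sok2, 3 of 3 members rose (3 adjusted over the list alone), median 4.58 (adjusted p = 1.78e-11, or 2.4e-06 with an estimated correlation). Of the general stress genes in that strain, 18 of 21 members rose (19 adjusted over the list alone), median 1.61 (adjusted p = 4.48e-18, or 0.0257 with an estimated correlation). Without sfl1-sok2 array 1 that median was 0.95 (adjusted p = 3.15e-14). In sfl1-yap6, HSP42 for a small heat shock protein (4.62 ± 0.46, adjusted p = 4.04e-12) and CAR2 for arginine use (5.27 ± 0.59, adjusted p = 1.51e-10) rose, while SUL1 (-4.18 ± 0.30, adjusted p = 3.5e-16) and DBP7, a helicase gene of ribosome making (-3.27 ± 0.34, adjusted p = 1.22e-11), fell. Of the general stress genes there, 21 of 21 members rose (21 adjusted over the list alone), median 2.69 (adjusted p = 3.2e-16, or 0.0955 with an estimated correlation). Of the ribosome biogenesis genes, 22 of 22 members fell (22 adjusted over the list alone), median -1.82 (adjusted p = 1.43e-13, or 0.215 with an estimated correlation). In sok2-yap6, PRM8, a pheromone-regulated gene (3.69 ± 0.23, adjusted p = 3e-19), rose and SUL1 (-4.00 ± 0.30, adjusted p = 1.88e-15) fell. Of its sulfur assimilation genes, 11 of 13 members fell (12 adjusted over the list alone), median -1.25 (adjusted p = 3.53e-14, or 0.0113 with an estimated correlation). In tec1-cup9, MDH2 for a cytosolic malate dehydrogenase rose (2.67 ± 0.50, adjusted p = 0.000938) and SRD1 fell (-3.15 ± 0.41, adjusted p = 1.21e-06). Of its filamentation MAPK genes, 2 of 12 members fell (4 adjusted over the list alone), median -0.34 (adjusted p = 1.1e-07, or 0.000135 with an estimated correlation). In tec1-skn7, HPF1 (2.85 ± 0.55, adjusted p = 0.000228) and the membrane protein gene MRH1 (2.50 ± 0.41, adjusted p = 2.92e-05) rose. Of its ergosterol genes, 10 of 12 members rose (10 adjusted over the list alone), median 0.61 (adjusted p = 0.000458, or 0.153 with an estimated correlation).

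**Figure D3:**
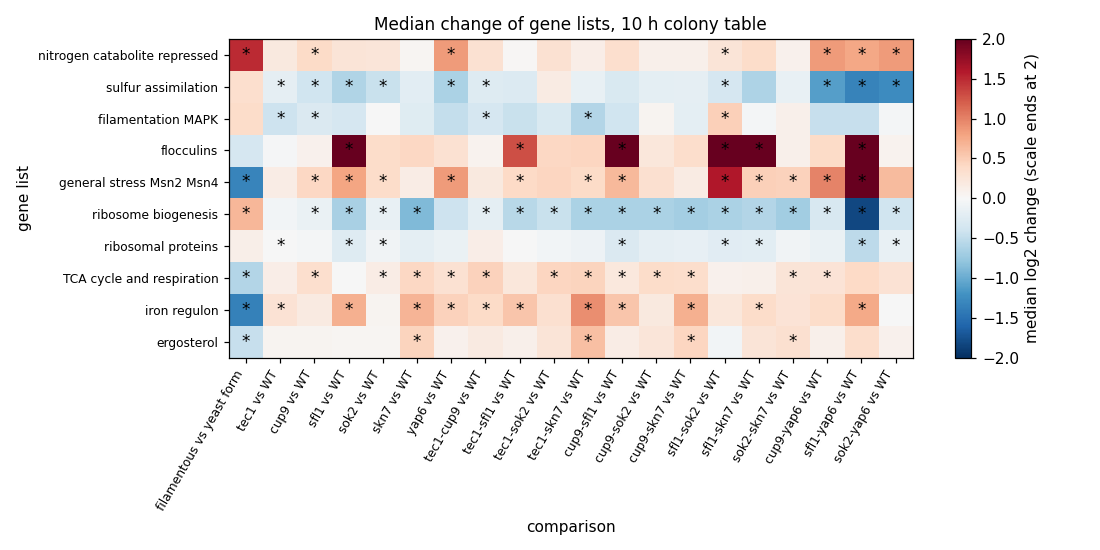
Median log2 change of 10 gene lists (vertical axis) in 20 comparisons of the 10 h colony table (horizontal axis), in colour on a scale that ends at 2. An asterisk marks an adjusted camera p under 0.05 with the preset correlation. The general stress list had a median of -1.32 in filamentous against yeast-form wild-type colonies and 2.69 in sfl1-yap6 against the filamentous wild type.

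The pairs ranged from 100 genes in tec1-cup9, where PTR2 had the largest rise, to 2593 in sfl1-yap6. In tec1-cup9, 79 higher and 21 lower genes passed, and the total was 43, 47 or 40 without wild-type array 1, 2 or 3 and 40, 291 or 17 without tec1-cup9 array 1, 2 or 3. For tec1-sfl1 there were 556 higher and 488 lower, or 513 or 381 without wild-type array 1 or 3 and 355 or 667 without tec1-sfl1 array 1 or 2. The tec1-sok2 strain gave 422 higher and 135 lower, or 284 or 172 without wild-type array 1 or 3 and 1866, 141 or 325 without tec1-sok2 array 1, 2 or 3. In tec1-skn7 there were 963 higher and 814 lower, or 1125 without wild-type array 3. Without CUP9 and SFL1, 812 higher and 1220 lower passed, or 1319 or 904 without cup9-sfl1 array 2 or 3. Without CUP9 and SOK2, 294 higher and 298 lower passed, or 232, 306 or 138 without wild-type array 1, 2 or 3 and 51 or 353 without cup9-sok2 array 2 or 3. Without CUP9 and SKN7, 251 higher and 532 lower passed, or 288, 425 or 131 without wild-type array 1, 2 or 3 and 51 without cup9-skn7 array 1. Loss of SFL1 with SOK2 gave 520 higher and 669 lower, or 664 without wild-type array 3 and 474 without sfl1-sok2 array 1. Loss of SFL1 with SKN7 gave 451 higher and 627 lower, or 662 or 567 without wild-type array 1 or 3 and 417 or 646 without sfl1-skn7 array 1 or 3. Loss of SOK2 with SKN7 gave 206 higher and 202 lower, or 172, 229 or 111 without wild-type array 1, 2 or 3 and 142 or 109 without sok2-skn7 array 1 or 2. The yap6 pairs gave 752 higher and 474 lower (cup9-yap6) and 1328 higher and 1265 lower (sfl1-yap6), totals that no single array moved by more than 1.5 times, and 544 higher and 284 lower (sok2-yap6), or 511 without wild-type array 3 and 408 without sok2-yap6 array 1.

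For each pair, the change of the double mutant was compared with the sum of the changes of its single mutants. FLO10 was far lower in tec1-sfl1 than that sum (-3.76 ± 0.32, adjusted p = 9.48e-13), and FLO1, another flocculin gene, was far higher in sfl1-sok2 (4.04 ± 0.44, adjusted p = 6.29e-09). In sfl1-yap6, the chaperone genes HSP82 (4.15 ± 0.48, adjusted p = 8.48e-09) and BTN2 (3.98 ± 0.64, adjusted p = 1.32e-05) lay above the sum, and TPO2 (-4.68 ± 0.84, adjusted p = 9.87e-05) and PRM7 (-3.94 ± 0.67, adjusted p = 3.62e-05) below it. Of the general stress genes in this contrast, 9 of 21 members rose (12 rose and 1 fell adjusted over the list alone), median 1.26 (adjusted p = 9.04e-05, or 0.819 with an estimated correlation). Among ribosome biogenesis genes, 8 of 22 members fell (12 adjusted over the list alone), median -0.87 (adjusted p = 1.65e-07, or 0.819 with an estimated correlation). TPO2 (-6.14 ± 0.84, adjusted p = 7.67e-06) and HSP30 (-4.02 ± 0.88, adjusted p = 0.0092) lay below the sum in sok2-yap6. Of the iron regulon in sfl1-skn7, 7 of 14 members fell (9 adjusted over the list alone), median -0.98 (adjusted p = 0.000119, or 0.433 with an estimated correlation). COS8 lay below the sum (-2.23 ± 0.44, adjusted p = 0.00666; adjusted p = 0.0574 without skn7 array 1). In the flocculin list for tec1-sfl1 the median was 0.21 while its mean was -0.93 and the camera test pointed down. That call did not hold with an estimated correlation.

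Beside a count of 0 with limma, the number of genes at an unadjusted p under 0.05 is given as unadjusted. The departures from the sum counted 463 higher and 335 lower genes in sfl1-yap6, or 524 without sfl1 array 3 and 438 without sfl1-yap6 array 3. For sfl1-skn7 they were 326 higher and 230 lower, or 288, 331 or 223 without wild-type array 1, 2 or 3, 1146 or 32 without sfl1 array 2 or 3, 0 (1106 unadjusted) or 1013 without skn7 array 1 or 2 and 840, 118 or 247 without sfl1-skn7 array 1, 2 or 3. For tec1-cup9 they were 15 higher and 131 lower, or 41 or 69 without wild-type array 2 or 3, 70 without tec1 array 2, 97 or 70 without cup9 array 4 or 5 and 25, 499 or 17 without tec1-cup9 array 1, 2 or 3. In sok2-yap6, 17 higher and 33 lower passed, or 30 without wild-type array 3, 27 or 25 without sok2 array 1 or 2 and 27 or 32 without yap6 array 1 or 2. In cup9-sok2, 3 higher and 43 lower passed, or 23, 8 or 26 without wild-type array 1, 2 or 3, 79, 119, 21 or 17 without cup9 array 2, 3, 4 or 5, 29 or 4 without sok2 array 2 or 3 and 110, 0 (609 unadjusted) or 24 without cup9-sok2 array 1, 2 or 3. In tec1-sok2, 3 higher and 19 lower passed, or 4, 1 or 6 without wild-type array 1, 2 or 3, 6, 2, 6 or 46 without tec1 array 1, 2, 4 or 5, 2 or 1 without sok2 array 2 or 3 and 978, 1 or 1 without tec1-sok2 array 1, 2 or 3. The 6 genes of cup9-sfl1 were FLO1, IDH1, IDH2, RME1, TIS11 and YHR138C, or 0 (596 unadjusted), 1 or 0 (555 unadjusted) without wild-type array 1, 2 or 3, 0 (605 unadjusted), 0 (599 unadjusted), 16, 10 or 0 (595 unadjusted) without cup9 array 1, 2, 3, 4 or 5, 0 (604 unadjusted), 0 (539 unadjusted) or 3 without sfl1 array 1, 2 or 3 and 3 or 0 (511 unadjusted) without cup9-sfl1 array 1 or 3. The 4 of sok2-skn7 were HTL1, COS12, YBL029W and YDR541C, or 0 (469 unadjusted) without wild-type array 1, 0 (355 unadjusted) without sok2 array 2, 0 (310 unadjusted) without skn7 array 1 and 2, 12 or 0 (306 unadjusted) without sok2-skn7 array 1, 2 or 3. The 3 of sfl1-sok2 were FLO1, PRM7 and YFL051C, or 1 or 1 without wild-type array 1 or 3, 18, 14 or 1 without sfl1 array 1, 2 or 3, 1 or 1 without sok2 array 2 or 3 and 19, 7 or 15 without sfl1-sok2 array 1, 2 or 3. The 2 of tec1-sfl1 were FLO10 and FUS1, or 1 or 1 without wild-type array 2 or 3, 9 without sfl1 array 2 and 1 or 11 without tec1-sfl1 array 1 or 3. With limma, 0 genes passed in tec1-skn7 (225 unadjusted), cup9-skn7 (490) and cup9-yap6 (163). CUP9 was not at the level of a deleted gene in cup9-yap6, so its count does not measure a pair lacking both genes. Leaving out 1 array gave 1 gene in cup9-skn7 without cup9 array 3 and otherwise no gene in these pairs. The names given in full for small counts include some chosen after their values were seen.

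In the SC medium table, the altered genes were again read first. IRA1, a gene for a protein that switches Ras off, fell in the ira1 strain (-4.34 ± 0.55, adjusted p = 0.00607), where 1 array read the lowest value of the table, so the size depends on the floor. IRA1 did not pass with a floor at 20 (adjusted p = 0.108) or in a fit of only the groups compared (0.257, from 0.000169 to 0.257 over all alternatives). IRA2 was dim in the wild type (3.13 ± 2.17, SD, n = 4) and did not pass in the ira2 strain. RAS2 rose in the strain carrying the dominant negative RAS2A22 allele on a plasmid (3.24 ± 0.48, adjusted p = 0.00198), with deposited values of 650 and 734 against 46 to 111 in the wild type. In the strain with the dominant active RAS2V19 allele, RAS2 read 64 and 31. In the strains labelled ras1 ras2 pde2, PDE2, the gene for the high-affinity cAMP phosphodiesterase, read 1 in all 6 arrays and RAS2 read 1 to 3. RAS1 read 136 to 364 there against 23 to 41 in the wild type, which goes against the labelled ras1 deletion, and the cause was not tested. URA3, the plasmid marker, read 835 and 1199 in wild-type arrays 1 and 2 but 61 and 51 in arrays 3 and 4, so the 4 wild-type arrays were not alike. With wild-type arrays 1 and 2 alone, the genes that passed numbered 76 in ira1, 39 in ira1RA, 90 in ira2, 44 in ras2v19 and 330 in ras2a22. With arrays 3 and 4 alone they numbered 303, 315, 630, 339 and 923, and with the array set as a block 93, 55, 125, 48 and 473.

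Loss of IRA1, which should leave Ras more active, lowered GLK1 for glucokinase (-2.41 ± 0.26, adjusted p = 0.00427) and MIX14, a mitochondrial protein gene (-3.02 ± 0.34, adjusted p = 0.00427). STF2, for a protein of desiccation tolerance, fell (-4.42 ± 0.67, adjusted p = 0.0174), but not at adjusted p = 0.0659 without wild-type array 3 and 0.0592 without ira1 array 2. Of the TCA cycle and respiration genes, no member of 25 passed singly (6 fell adjusted over the list alone), median -0.69 (adjusted p = 2.65e-05, or 0.57 with an estimated correlation). In a fit of only the groups compared, GLK1 (adjusted p = 0.174, from 7.6e-06 to 0.174 over all alternatives), MIX14 (0.185, from 0.000271 to 0.185) and STF2 (0.111, from 0.000233 to 0.111) did not pass. FLO11 gave 1.41 ± 0.40, adjusted p = 0.169. In all, 0 higher and 13 lower genes passed with limma, and the total was 66 or 7 without wild-type array 1 or 3 and 121 or 77 without ira1 array 1 or 2. With IRA1 R-to-A on a plasmid in the same deletion (ira1RA), FLO11 rose (2.79 ± 0.40, adjusted p = 0.0312), though not at adjusted p = 0.092 or 0.0526 without wild-type array 3 or 4 and 0.0877 without ira1RA array 2. In a fit of only the groups compared its adjusted p was 0.244 (from 0.00115 to 0.244 over all alternatives). Of the histone genes in ira1RA, no member of 8 passed singly (6 fell adjusted over the list alone), median -0.89 (adjusted p = 5.47e-07, or 0.0961 with an estimated correlation). Of the ribosomal protein genes, no member of 126 passed singly (none adjusted over the list alone), median -0.37 (adjusted p = 6.85e-13, or 0.477 with an estimated correlation). After quantile normalization that median was -0.12. Of the genes called in ira1, 9 of 13 had an array at the lowest value of the table, so their calls depend on the floor. The 4 genes of ira1RA were FLO11, SAP185, TAP42 and YAR009C, with both ira1RA arrays of SAP185 and TAP42 at that floor, and the total was 28 or 2 without wild-type array 1 or 3 and 47 or 16 without ira1RA array 1 or 2. Between ira1 and ira1RA, 2 higher and 5 lower passed, among them ADH4 for an alcohol dehydrogenase (-2.68 ± 0.39, adjusted p = 0.0234; adjusted p = 0.12 without ira1RA array 2), and the total was 69 or 52 without ira1 array 1 or 2 and 38 without ira1RA array 1. Of the ribosomal protein genes, no member of 126 passed singly (none adjusted over the list alone), median 0.49 (adjusted p = 9.46e-26, or 0.168 with an estimated correlation), with a median of 0.22 after quantile normalization.

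Loss of IRA2, the partner of IRA1, raised FLO11 (2.98 ± 0.40, adjusted p = 0.00269) and FRE4 for a ferric reductase (3.34 ± 0.54, adjusted p = 0.00742). INH1, for the inhibitor of the mitochondrial ATP synthase, fell (-3.69 ± 0.66, adjusted p = 0.016), but not at adjusted p = 0.0502 without wild-type array 3 and 0.0958 without ira2 array 1. Of the TCA cycle and respiration genes, 5 of 25 members fell (12 adjusted over the list alone), median -0.92 (adjusted p = 3.42e-08, or 0.125 with an estimated correlation). Of the flocculins, 1 of 5 members rose (2 adjusted over the list alone), median 1.86 (adjusted p = 0.0291, or 0.125 with an estimated correlation). The flocculin call was lost at adjusted p = 0.142 or 0.0674 without ira2 array 1 or 2. In a fit of only the groups compared, FLO11 (adjusted p = 0.0943, from 0.000295 to 0.0943 over all alternatives) and FRE4 (0.195, from 0.000271 to 0.195) did not pass, and with the replicate number as a block INH1 did not (0.104, from 4.77e-05 to 0.104). In all, 9 higher and 107 lower genes passed, 63 of them with an array at the floor, and the total was 236, 50 or 68 without wild-type array 1, 3 or 4 and 299 without ira2 array 2. The median change of all genes was -0.18 as scaled and -0.04 after quantile normalization, so the falls are smaller by that shift.

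Against all 4 wild-type arrays, which were not alike, the activated RAS2V19 allele gave few calls. It gave more against either pair of them alone, as given above. Wild-type arrays 3 and 4 also had a smaller share of values at 1 than the ras2v19 arrays. HMT1, for an arginine methyltransferase, rose (1.32 ± 0.20, adjusted p = 0.0346), but not at adjusted p = 0.0974 or 0.0562 without wild-type array 3 or 4 and 0.0589 without ras2v19 array 2. PDE2 gave 1.85 ± 0.40, adjusted p = 0.0921 and FLO11 0.92 ± 0.40, adjusted p = 0.358. Of the glycolysis and fermentation genes, no member of 16 passed singly (1 rose adjusted over the list alone), median 0.36 (adjusted p = 0.00565, or 0.607 with an estimated correlation), with a median of 0.18 after quantile normalization. Of the hexose transporter genes, no member of 9 passed singly (1 rose adjusted over the list alone), median 0.67 (adjusted p = 0.0456, or 0.377 with an estimated correlation). The glycolysis call was lost at adjusted p = 0.068 or 0.0648 without wild-type array 3 or 4, and that of the hexose transporters at 0.0662, 0.072 or 0.0661 without wild-type array 1, 3 or 4 and 0.357 without ras2v19 array 2. HMT1 did not pass with quantile normalization (adjusted p = 0.0778) or in a fit of only the groups compared (0.346, from 8.32e-05 to 0.346 over all alternatives). In all, 2 higher and 6 lower genes passed, 7 of 8 with an array at the floor, and the total was 28 or 1 without wild-type array 1 or 3 and 192 or 32 without ras2v19 array 1 or 2.

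The dominant negative RAS2A22 allele raised stress genes, among them GRE1 (7.37 ± 1.14, adjusted p = 0.00255) and DDR2 (5.80 ± 0.63, adjusted p = 0.000243), and HSP12 for a membrane-protecting stress protein (7.56 ± 1.59, adjusted p = 0.0132; adjusted p = 0.0857 or 0.119 without ras2a22 array 1 or 2). Among general stress genes, 17 of 21 members rose (19 adjusted over the list alone), median 4.53 (adjusted p = 4.22e-22, or 8.66e-05 with an estimated correlation). Of the TCA cycle and respiration genes, 13 of 25 members rose (20 adjusted over the list alone), median 1.46 (adjusted p = 3.85e-14, or 0.0132 with an estimated correlation). Of the oxidative stress genes, 5 of 13 members rose (7 adjusted over the list alone), median 0.87 (adjusted p = 8.38e-07, or 0.0132 with an estimated correlation). The zinc-responsive genes ZPS1 (-5.70 ± 0.22, adjusted p = 2.77e-08) and ZRT1 (-4.21 ± 0.27, adjusted p = 2.85e-06) fell, as did CIT2 for a citrate synthase (-4.30 ± 0.23, adjusted p = 5.48e-07). Among ribosome biogenesis genes, 6 of 22 members fell (11 adjusted over the list alone), median -1.16 (adjusted p = 2.84e-07, or 0.0736 with an estimated correlation). Of the amino acid biosynthesis genes, 6 of 25 members fell (12 adjusted over the list alone), and their median fell by 1.00 (adjusted p = 8.38e-07, or 0.0736 with an estimated correlation). HSP12 did not pass with only wild-type arrays 1 and 2 (adjusted p = 0.0772, from 1.38e-05 to 0.119 over all alternatives). In all, 209 higher and 236 lower genes passed, 114 of them with an array at the floor, and the total was 188 or 136 without ras2a22 array 1 or 2.

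In the strains labelled ras1 ras2 pde2, cAMP was supplied from outside to ask which genes differ with it. With 2 mM against 0 mM, SAM1 for S-adenosylmethionine synthesis (5.85 ± 0.42, adjusted p = 4.31e-06), HXK2 for hexokinase (5.69 ± 0.32, adjusted p = 8.32e-07), ZPS1 (5.27 ± 0.26, adjusted p = 2.6e-07) and FLO11 (4.47 ± 0.46, adjusted p = 5.68e-05) rose. FLO11 read 13 and 26 at 0 mM, 221 at 0.5 mM, 433 at 1 mM and 418 and 396 at 2 mM in deposited intensity. DDR2 (-7.15 ± 0.73, adjusted p = 5.82e-05), INH1 (-7.15 ± 0.76, adjusted p = 7.27e-05) and the hexose transporter gene HXT5 (-7.01 ± 1.52, adjusted p = 0.0061) fell. At 2 mM DDR2 read 66 and 13, INH1 2 and 19 and HXT5 5 and 7 in deposited intensity. Most of these values lie under the array median of 29, so the sizes of these falls rest on weak signals. With the slope over the concentration, the rises did not pass for SAM1 (adjusted p = 0.0522, from 3.3e-10 to 0.0522 over all alternatives), HXK2 (0.073, from 9.88e-11 to 0.073), ZPS1 (0.133, from 7.09e-12 to 0.133) and FLO11 (0.0689, from 4.29e-07 to 0.0689). ZPS1 read 2817 at 0.5 mM and 3321 at 1 mM but 2289 and 2183 at 2 mM. In the general stress list, 19 of 21 members fell (20 adjusted over the list alone), median -5.77 (adjusted p = 7.62e-17, or 0.000321 with an estimated correlation). Of the TCA cycle and respiration genes, 1 of 25 members rose and 20 fell (1 rose and 21 fell adjusted over the list alone), median -2.08 (adjusted p = 6.11e-15, or 0.0171 with an estimated correlation). Of the ribosomal protein genes, 107 of 126 members rose (121 adjusted over the list alone), median 1.33 (adjusted p = 1.69e-32, or 0.0297 with an estimated correlation), with a median of 0.85 after quantile normalization. Of the ribosome biogenesis genes, 17 of 22 members rose (19 adjusted over the list alone), median 2.63 (adjusted p = 4.03e-13, or 0.0186 with an estimated correlation). Of the amino acid biosynthesis genes, 19 of 25 members rose (19 adjusted over the list alone), median 1.82 (adjusted p = 3.1e-10, or 0.0229 with an estimated correlation). In all, 673 higher and 419 lower genes passed, 89 of them with an array at the floor, and the total was 648 or 677 without 0mM_cAMP array 1 or 2 and 653 or 702 without 2mM_cAMP array 1 or 2. Since 0 mM differs from all other concentrations in strain number and plasmid too, these changes cannot be ascribed to cAMP alone. HIS3 read 49 and 41 at 0 mM and 164 to 266 at the other concentrations.

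**Figure D4:**
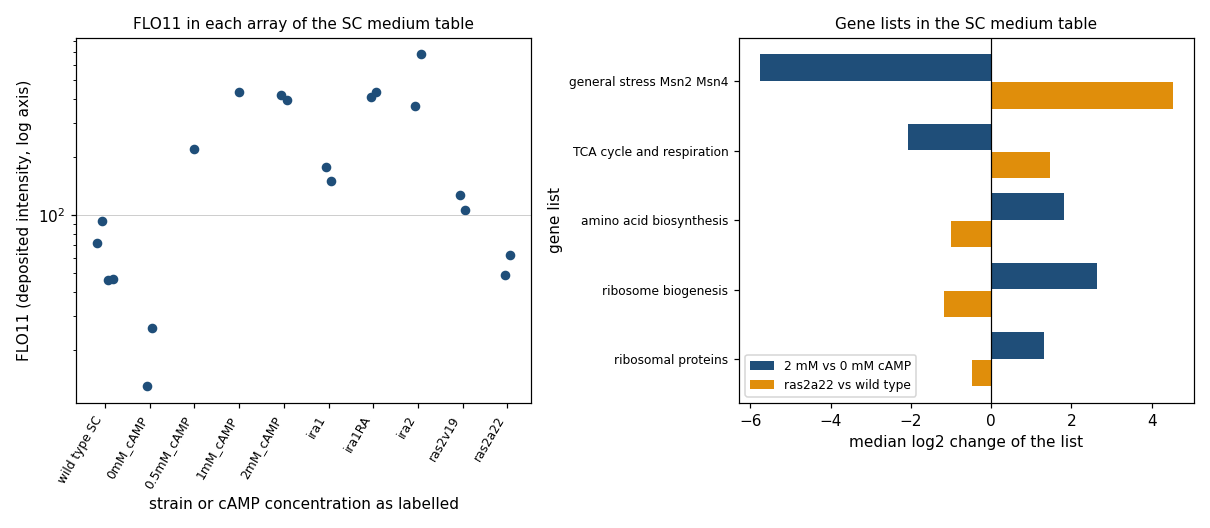
Left, deposited intensity of FLO11 (vertical log axis) in each of the 20 arrays of the SC medium table, by strain or cAMP concentration; each point is an array, and FLO11 read 13 and 26 at 0 mM and 418 and 396 at 2 mM. Right, median log2 change of 5 gene lists for 2 mM against 0 mM cAMP (blue) and for ras2a22 against the wild type (orange); the general stress list stood at -5.77 and 4.53.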

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

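The tests chosen only after the result was seen were those of an undeleted gene and of mixed RNA in the libraries labelled tec1 replicate 1 and cup9 replicate 4, all those of CUP9 in cup9-yap6, the permuted residuals of the departures, and the draws without the libraries at odds with their labels.

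TEC1 and CUP9 each had 1 library far from the others of its strain. TEC1 read 8.68 in the library labelled tec1 replicate 1 against at most 5.37 in the other 4, and CUP9 read 8.21 in the library labelled cup9 replicate 4 against at most 4.34. PTR2 followed CUP9, at 11.54 in the first library (7.03 or less in the other tec1 arrays) and 7.13 in the second (11.52 or more in the other cup9 arrays). CUP9 read 4.07 in the first library, where the other tec1 arrays read 7.88 or more. Such lone arrays were sought in 172 sets of values of a group of 4 to 6 arrays, and 21 were found where chance gives about 8.6.

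A labelled gene left undeleted, with no exchange of libraries, is argued against by CUP9, which lay at -3.81 from the lowest other tec1 array, and by TEC1, at -2.93 from the lowest other cup9 array. Mixed RNA of both strains is argued against by CUP9 at -0.27 from the highest other cup9 array and TEC1 at -0.80 from the highest other tec1 array. For TEC1, CUP9 and PTR2 each library read like the arrays of the other strain, as an exchange of the 2 libraries would give. Beyond these genes, an exchange of the 2 libraries stays open. On an axis of all other genes from the tec1 (0) to the cup9 (1) arrays, they lay at 0.599 and 0.0489, on the sides of an exchange, yet 3 of 4 other cup9 arrays lay under 0.5 (0.490, 0.386 and 0.353) and 1 of 4 tec1 arrays above (0.537), so the axis could not decide. No biological explanation was tested.

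CUP9 in the 3 cup9-yap6 libraries did not fall to the level of a deleted gene, though PTR2 rose. A probe set blind to the deletion is argued against by CUP9 in the other 4 double deletions with cup9, where the smallest change was -3.06. Libraries of the yap6 deletion alone are argued against by PTR2, which was higher than in yap6 by 2.98 (95 percent interval 1.33 to 4.62). With all arrays PTR2 had an adjusted p of 0.832, and the 0.00145 without the libraries labelled tec1 replicate 1 and cup9 replicate 4 came from a fit added after that. Over all genes the 2 strains differed little. With limma, 1 gene was called with all arrays and 2 without those libraries, and 177 had an unadjusted p under 0.05. Cells or gene copies that kept CUP9 could explain it and stay open, with CUP9 at -1.09 from yap6 (interval -2.36 to 0.18 and adjusted p = 0.998 with all arrays, -1.57 to -0.61 and 0.0527 without those libraries), and no biological explanation was tested.

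The changes of sfl1, skn7 and yap6 resembled each other, and the ribosome biogenesis list was called lower in sfl1 and skn7 (0.654 and 0.627 with an estimated correlation) but not in yap6 (median -0.42, adjusted p = 0.151), the general stress list higher in sfl1 and yap6 (0.447 and 0.605) but not in skn7 (median 0.15, adjusted p = 0.214), differences between strains that were not tested. The covariance of the sfl1 and skn7 changes was 0.206. Simulated unchanged groups with shared controls gave 0.0253 on average and at most 0.0787 in their 95 percent range. This argues against the random spread of shared control arrays as the whole cause of the resemblance. An offset common to the real wild-type arrays could not appear in the simulation and stays open. The median of ribosome biogenesis in skn7 was -0.83 after quantile normalization and -0.88 as deposited. The deposited values were already made with RMA, so a further normalization could change little. Array brightness as the cause of that fall therefore stays open. Over all 20 low-ammonium strains, 70.5 percent of the variance of this list lay between strains. Permuted labels gave 31.1 percent on average and 68.4 at most (permutation p = 1e-05, the smallest that 100000 permutations can give). Arrays that vary in this list whatever the strain are thus argued against for the strains as a set. That set includes sfl1-yap6, with the lowest array means (7.63, 7.75 and 6.72). For sfl1, skn7 and yap6 alone the share decides nothing. Growth or hybridization in batches may explain the shift and cannot be told apart from the deletions, since 0 groups name a batch in the labels; an effect of losing these factors stays open, as untested beyond this.

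Other lone arrays are given as values. Among yeast-form arrays these were PTR2 in replicate 1 (5.79, nearest 6.15), PHD1 in replicate 2 (6.90, nearest 6.41), the mean of the sulfur assimilation list in replicate 5 (9.56) and of the iron regulon in replicate 4 (8.22). Among tec1 arrays, replicate 2 stood apart for RAS2 (9.89), PDE2 (6.25) and the mean of the ribosome biogenesis list (9.75), and replicate 4 for URA3 (3.20). The tec1 replicate 3 array stood apart for IME1 (5.50) and the means of the histone (11.34) and meiosis lists (3.68), and the library labelled tec1 replicate 1 for that of glycolysis (12.27). PDE2 in cup9 replicate 3 (7.42) and the mean of the haploid-specific list in cup9 replicate 5 (4.19) also stood apart. In SC medium, SFL1 in wild-type replicate 1 (3.69) and the mean of the a-specific list in wild-type replicate 2 (3.64) did. Chance gives about 1 such array in 20 sets.

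Departures of a pair from the sum of its single deletions were tested for each gene. RAS2 lay at -1.28 in tec1-cup9 (adjusted p = 0.0152), but not at adjusted p = 0.0573 without wild-type array 2 and 0.0891 or 0.164 without tec1-cup9 array 1 or 3. In cup9-sok2 RAS2 lay at -1.26 (adjusted p = 0.0411), but not at adjusted p = 0.0667, 0.139 or 0.0807 without wild-type array 1, 2 or 3, 0.0753 or 0.0934 without cup9 array 4 or 5, 0.0583, 0.0689 or 0.144 without sok2 array 1, 2 or 3 and 0.215 or 0.0619 without cup9-sok2 array 2 or 3. In sfl1-skn7, SOK2 lay at 1.00 (adjusted p = 0.0267), which was lost at adjusted p = 0.0512 without wild-type array 3, 0.156 without sfl1 array 3, 0.138 without skn7 array 1 and 0.0858 without sfl1-skn7 array 2. LEU2 lay at -0.66 (adjusted p = 0.0484), which was lost at adjusted p = 0.0685, 0.0665 or 0.0977 without wild-type array 1, 2 or 3, 0.0633, 0.0539 or 0.108 without sfl1 array 1, 2 or 3, 0.16 or 0.0719 without skn7 array 1 or 3 and 0.136 or 0.0842 without sfl1-skn7 array 2 or 3. SFL1 in sfl1-skn7 (-0.87, adjusted p = 0.0362), YAP6 in sfl1-yap6 (1.29 ± 0.31, adjusted p = 0.00313) and SOK2 in sok2-yap6 (1.57 ± 0.29, adjusted p = 0.000779) are themselves deleted in 2 of the strains compared. Their departures follow from that absence and say nothing of an interaction, and that of SFL1 was lost at adjusted p = 0.0684 or 0.0913 without wild-type array 1 or 3, 0.0719 or 0.152 without sfl1 array 1 or 3, 0.176 or 0.0593 without skn7 array 1 or 3 and 0.159 without sfl1-skn7 array 2. YAP6 in sfl1-skn7 (0.92, adjusted p = 0.0474) says nothing of it either, since YAP6 already read 2.85 to 3.46 in sfl1 and 3.02 to 3.20 in skn7, near the 2.32 to 3.07 of strains lacking it. That departure was lost at adjusted p = 0.0771 or 0.117 without wild-type array 1 or 3, 0.0615 or 0.189 without sfl1 array 1 or 3, 0.156 or 0.0658 without skn7 array 1 or 3 and 0.137 or 0.0615 without sfl1-skn7 array 2 or 3.

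Other splits of the same arrays, 100 per pair, move the effects of the single deletions into the departure, so they cannot decide whether chance gave these counts. The splits as large, with the real count and the highest other, were 2 for tec1-cup9 (146 and 183), 1 for cup9-sok2 (46 and 34), 2 for sfl1-skn7 (556 and 1140), 31 for tec1-sfl1 (2 and 1828), 5 for tec1-sok2 (22 and 615), 21 for cup9-sfl1 (6 and 2270) and 29 for sfl1-sok2 (3 and 1309). For sok2-skn7 there were 16 (4 and 1617), for sfl1-yap6 7 (798 and 1773) and for sok2-yap6 16 (50 and 479). Residuals of the model without a departure, permuted over the same arrays in 100 draws with the real one, left those effects in place. The draws as large, with the real one, were 3 of 100 for tec1-cup9 (highest other 372) and 1 for cup9-sok2 (highest other 17). They were 4 for sok2-skn7 (highest other 204), 1 for sfl1-yap6 (highest other 776) and 3 for sok2-yap6 (highest other 97). Larger shares came from tec1-sfl1 (7, highest other 66), tec1-sok2 (12, highest other 1717) and cup9-sfl1 (5, highest other 48). The same held for sfl1-sok2 (21, highest other 119) and sfl1-skn7 (6, highest other 1484). The test was chosen after seeing the data, and its shares were not adjusted over the pairs. With only 100 draws, it cannot exclude chance for any pair. The tec1 and cup9 groups hold the 2 libraries at odds with their labels. Without both, the draws as large were 2 of 100 for tec1-cup9 (76 genes, highest other 586) and 2 for cup9-sok2 (18, highest other 34). They were 10 for tec1-sfl1 (2 genes, highest other 33) and 12 for tec1-sok2 (6, highest other 1277). For cup9-sfl1 they were 9 (9 genes, highest other 71) and for cup9-yap6 8 (1 gene, highest other 15). For tec1-skn7, cup9-skn7 and cup9-yap6, limma called 0 genes (225, 490 and 163 at an unadjusted p under 0.05). With such a count all 100 splits and all 100 draws are as large by definition, so they decide nothing. The highest split gave 2016, 1736 and 1157 genes and the highest draw 5, 9 and 26. Since CUP9 was not at a deleted level in cup9-yap6, that departure is not one of a pair lacking both genes. The counts moved without 1 array: tec1-cup9 17 to 499 (lowest without tec1-cup9 replicate 3, highest without tec1-cup9 replicate 2), cup9-sok2 0 (609 at an unadjusted p under 0.05, without cup9-sok2 replicate 2) to 119 (without cup9 replicate 3), and sfl1-skn7 0 (1106 at an unadjusted p under 0.05, without skn7 replicate 1) to 1146 (without sfl1 replicate 2). The other counts, and those without each array, stand beside these departures in the results.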

How the results depend on the processing

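Alternatives chosen only after the result was seen were gene lists without 1 array, both libraries labelled tec1 replicate 1 and cup9 replicate 4 left out, the floor at 20, only wild-type arrays 1 and 2 or 3 and 4 of SC medium, and the array set as a block. Of 32365 values of 2192 named gene and comparison pairs over all alternatives, 30690 kept their direction and side of the threshold, 1072 no longer passed, 595 came to pass and 8 reversed. All 8 reversals were of URA3 in SC medium. With the replicate number as a block, only wild-type arrays 1 and 2, or the array set as a block, URA3 gave -1.92 in ira1 and -1.99 in ira1RA. With only wild-type arrays 3 and 4 it gave 1.51 in ira2 and 1.95 in ras2v19. Of 635 counts under an alternative, 377 lay within 1.5 times the count reported. The TEC1 call in tec1 ran from an adjusted p of 1.01e-12 to 0.197 over its alternatives, that of IRA1 in ira1 from 0.000169 to 0.257, and that of FLO11 from 4.29e-07 to 0.0689 for cAMP, 0.00115 to 0.244 in ira1RA and 0.000295 to 0.0943 in ira2. FLO11 in sok2 (0.00723 to 0.476) and tec1-cup9 (0.0121 to 0.472) came to pass in the fit of only the groups compared. Of 228 calls of gene lists, 25 were made with an estimated correlation between genes, 84 were lost without 1 of some arrays, 5 medians moved by over 1.5 times without 1 array, and the median of 1 list turned with quantile normalization (ribosomal proteins in ira2, 0.03 to -0.02). The median change of all genes in ira2 was -0.18, and -0.04 after quantile normalization; that of cAMP was 0.13, and 0.14 after it. Quantile normalization moved the share of higher genes among the called by over 10 points for tec1 by cup9 (10.3 to 20.4 percent), tec1 by sok2 (13.6 to 28.6), cup9 by sfl1 (16.7 to 28.6), ira1RA (50 to 66.7) and ras2v19 (25 to 50). In departures with at most 7 genes it did so for tec1 by sfl1 (50 to 25), sfl1 by sok2 (33.3 to 57.1) and sok2 by skn7 (25 to 60). For cup9 by skn7 no gene was called before it and 1 gene, higher, after it. The floor of intensity limits weak genes in SC medium, where 6.77 to 25.6 percent of the values of an array were at 1.

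A pair written with by is the departure from the sum, and beside a count of 0 with limma stands the number at an unadjusted p under 0.05. The counts that moved by over 1.5 times are given by setting, and the cause was not tested. The mean of the probe sets of a gene and the slope over the cAMP concentration moved no count by that much. Quantile normalization gave 33 for cup9, 4 for tec1 by sfl1, 1 for cup9 by skn7, 7 for sfl1 by sok2, 9 for ira1RA, 2 for ras2v19 and 4 for ira1 against ira1RA. Dim genes left out gave 95 for tec1 by cup9, 1 for tec1 by sfl1, 3 for cup9 by sfl1, 27 for cup9 by sok2, 0 (524 unadjusted) for sfl1 by sok2, 2 for sok2 by skn7, 53 for ira1, 13 for ira1RA and 16 for ras2v19. Trend and robust eBayes gave 4 for tec1 by sfl1, 2 for cup9 by skn7, 76 for ira1, 25 for ira1RA, 198 for ira2, 51 for ras2v19 and 15 for ira1 against ira1RA. A fit of only the groups compared gave 0 (820 unadjusted) for cup9, 217 for sok2, 2344 for yap6, 31 for tec1-cup9, 1874 for tec1-sfl1, 28 for tec1-sok2, 1361 for cup9-sok2, 1348 for cup9-skn7 and 1588 for sok2-skn7. The same fit gave 1848 for cup9-yap6, 19 for tec1 by cup9, 0 (736 unadjusted) for tec1 by sok2, 1 for tec1 by skn7, 289 for cup9 by sok2, 1 for cup9 by skn7, 5 for sfl1 by sok2, 4 for ira1 and 2 for ira1RA. The same fit gave 47 for ira2, 1 for ras2v19, 220 for ras2a22, 0 (351 unadjusted) for ira1 against ira1RA and 2426 for cAMP. The replicate number as a block gave 1 for tec1, 49 for tec1 by cup9, 4 for tec1 by sok2, 1 for cup9 by sfl1, 15 for cup9 by sok2, 60 for ira1, 22 for ira1RA, 68 for ira2 and 35 for ras2v19. The same setting gave 294 for ras2a22 and 13 for ira1 against ira1RA. Both libraries at odds with their labels left out gave 14 for tec1, 76 for tec1 by cup9, 6 for tec1 by sok2, 18 for cup9 by sok2 and 1 for cup9 by yap6. The floor at the 25th percentile gave 75 for ira1, 22 for ira1RA, 84 for ras2v19, 765 for ras2a22 and 11 for ira1 against ira1RA. The floor at 20 gave 133 for ira1, 104 for ira1RA, 207 for ira2, 127 for ras2v19, 826 for ras2a22, 71 for ira1 against ira1RA and 1748 for cAMP. Only wild-type arrays 1 and 2 gave 76 for ira1, 39 for ira1RA and 44 for ras2v19. Only wild-type arrays 3 and 4 gave 303 for ira1, 315 for ira1RA, 630 for ira2, 339 for ras2v19 and 923 for ras2a22. The array set as a block gave 93 for ira1, 55 for ira1RA and 48 for ras2v19.

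Without 1 array, the count ran as follows: tec1 1 to 14, cup9 6 to 48, sfl1 485 to 1761, sok2 33 to 56, skn7 658 to 2214, yap6 815 to 1115, tec1-cup9 17 to 291 and tec1-sfl1 355 to 733. Further ranges without 1 array were tec1-sok2 141 to 1866, tec1-skn7 1125 to 1451, cup9-sfl1 904 to 2415, cup9-sok2 51 to 701, cup9-skn7 51 to 787, sfl1-sok2 474 to 1175, sfl1-skn7 417 to 1267 and sok2-skn7 109 to 336. Further ranges without 1 array were sok2-yap6 408 to 1042, tec1 by cup9 17 to 499, tec1 by sfl1 1 to 11, tec1 by sok2 1 to 978, cup9 by sfl1 0 (596 unadjusted) to 16, cup9 by sok2 0 (609 unadjusted) to 119, cup9 by skn7 0 (433 unadjusted) to 1 and sfl1 by sok2 1 to 19. Further ranges without 1 array were sfl1 by skn7 0 (1106 unadjusted) to 1146, sok2 by skn7 0 (469 unadjusted) to 12, sfl1 by yap6 438 to 1013, sok2 by yap6 25 to 64, ira1 7 to 121, ira1RA 2 to 47, ira2 50 to 299 and ras2v19 1 to 192. Further ranges without 1 array were ras2a22 136 to 625, ira1 against ira1RA 6 to 69 and cAMP 648 to 702.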

Other observations

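The tests of CUP9 and RAS1 with cAMP and of the lists in the first paragraph were picked for this part only after the result was seen, as were the splits without the libraries at odds with their labels, while the other splits were planned.

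In the strains labelled ras1 ras2 pde2, CUP9 was lower where cAMP was given, with a slope of -0.98 per mM (adjusted p = 0.0418), while 2 mM against 0 mM alone did not pass (-2.11 ± 1.12, adjusted p = 0.256) and the adjusted p ran from 0.00668 to 0.538 over all alternatives. Its deposited values were 191 and 172 at 0 mM, 67 at 0.5 mM, 54 at 1 mM and 40 and 44 at 2 mM cAMP. The 0 mM arrays are also of another strain number and plasmid, so cAMP and strain are confounded in these values. RAS1 read 136 and 148 at 0 mM, 203 at 0.5 mM, 224 at 1 mM and 364 and 269 at 2 mM, with a slope of 0.55 that did not pass (adjusted p = 0.0515, from 0.0301 to 0.851 over all alternatives). Of the sulfur assimilation genes in sfl1-yap6 colonies, 11 of 13 members fell (13 adjusted over the list alone), median -1.33 (adjusted p = 1.99e-06, or 0.215 with an estimated correlation). Of the a-specific cell type markers in tec1-sfl1, 3 of 6 members rose (4 adjusted over the list alone), median 0.46 (adjusted p = 0.000568, or 0.076 with an estimated correlation), and of the alpha-specific ones, 2 of 4 members rose (4 adjusted over the list alone), median 0.76 (adjusted p = 0.00447, or 0.185 with an estimated correlation).

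For the filamentous against the yeast form of the wild type, chance can be excluded: 2496 genes passed, the highest of the other 83 splits gave 231, and 1 of 84 splits was as large. Chance cannot be excluded for tec1 (7 genes, highest other 10, 4 of 56 splits as large) or cup9 (19, highest other 46, 4 of 56), whose arrays include the libraries labelled tec1 replicate 1 and cup9 replicate 4. Without both, 1 of 35 splits was as large for tec1 (14 genes, highest other 7) and 3 of 35 for cup9 (23, highest other 49). Those splits were chosen after seeing the data, so by them chance is not excluded for tec1, nor for cup9. With 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. The real value and the highest other were 1377 and 37 for sfl1, 65 and 0 for sok2, 2061 and 0 for skn7 and 1315 and 1 for yap6. They were 100 and 1 for tec1-cup9, 1044 and 0 for tec1-sfl1, 1777 and 0 for tec1-skn7, 2032 and 224 for cup9-sfl1, 592 and 0 for cup9-sok2 and 783 and 0 for cup9-skn7. For the remaining pairs they were 1189 and 1 for sfl1-sok2, 1078 and 0 for sfl1-skn7, 408 and 0 for sok2-skn7, 1226 and 0 for cup9-yap6, 2593 and 5 for sfl1-yap6 and 828 and 62 for sok2-yap6. For tec1-sok2 the real split gave 557 and the highest other 1359, in 2 of 10 splits as large; that split exchanged wild-type replicate 2 and tec1-sok2 replicate 1, which points to a structure of the samples.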
